A study of Mus musculus with 4 samples.

How the data were processed

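The series holds 4 droplet-based single-cell RNA libraries of live CD45+ cells, sorted by flow cytometry from subcutaneous B16-F10 mouse melanomas. Groups were taken from the sample labels. The isotype group (control antibody) and the triple group (antibodies against PD-1, 4-1BB and OX40) had 2 libraries each. The values used were UMI counts per gene and cell barcode as deposited, made with Cell Ranger 2.1.1 on the mm10 build per the submitters' processing notes. The kit chemistry, the annotation release and the rule that chose the barcodes are not given in the sources used here. The files held 27998 gene identifiers, of which 121 had a symbol shared with another identifier, and these were kept apart by identifier. Gene coordinates are from GENCODE vM21 (GRCm38, the build also called mm10), in which 27645 of the identifiers were found.

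The files held 22821 barcodes. The lowest UMI total of any barcode was 3156 and 2801 in isotype replicates 1 and 2, and 3257 and 3906 in triple replicates 1 and 2, so the files held no shallower barcodes. Median UMIs per barcode were 7648.5, 7336, 7849.5 and 8870 in the same order, with medians of 2057, 2024, 2143.5 and 2297 detected genes and of 1.88%, 1.94%, 1.88% and 1.99% mitochondrial UMIs. Cells with fewer than 500 detected genes (1, 1, 0 and 1) or more than 10% mitochondrial UMIs (31, 37, 40 and 51) were left out. Doublets were scored with Scrublet in scanpy 1.11.5 (expected rate 6%). Its own threshold called only 1 barcode in all 4 libraries and was not used. Instead, the highest scores were left out at a rate of 0.8% per 1000 barcodes, which took 339, 115, 254 and 378 barcodes. The 21576 cells kept were normalised to their totals for clustering only, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1) were used with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. T and NK cells were then clustered again at resolution 1.

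Clusters were given a class from marker lists fixed before the data were examined, as were the designs, the gene lists, the rule for named genes and a first set of alternatives. A name needed a marker score of at least 0.3 and at least 3 markers detected in at least 10% of the cluster's cells. Clusters led by markers of another class, or with a mean doublet score more than 2 times the median over clusters, stayed without a name. The thresholds of the naming rule were set after the files were seen. Cells of the T clusters are called CD8 T-like, CD4 conventional T-like and regulatory T-like, and the other classes are named in the same way. No annotation by the authors was used here, so the classes are rebuilt ones.

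Cells were not treated as replicates. UMI counts were summed per library and class, and classes with at least 30 cells in every library were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes are log2 and coded triple minus isotype, and levels are CPM of the class sum scaled by the TMM factors, so they differ slightly from counts over the class total. Levels over all CD45+ cells are not scaled. CD4 conventional T-like and NK-like cells fell under 30 cells in at least 1 library, so their tests, and the test of CD8 against CD4 cells, were not run. The numbers of cells per class were tested with the same edgeR method, with the library's total cells as offset. An exact two-sided permutation test is given beside shares, which for 2 libraries against 2 cannot go below 0.3333. The difference of the treatment effect between CD8 T-like and regulatory T-like cells was tested as an interaction, with the library as a term. Fixed gene lists with at least 5 tested members were run with camera in limma 3.58.1 (voom weights, preset correlation 0.01), with an estimated correlation beside it.

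CD8 T-like cells were clustered again at resolution 0.6 without the genes that passed in the class and without T cell receptor variable genes. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, which left out 0 cells, with macrophage-like cells as background. Genes named in the text followed a fixed rule. It took the genes of the 3 antibody targets and, among genes past the threshold with a mean log2 CPM of at least 5 and no overlap between groups, the largest changes in each direction. These were 12 per direction in CD8 T-like cells, 6 in the other main classes and 3 in the rest, and up to 4 members with the smallest p came from each list. Antigen receptor segments, ribosomal, mitochondrial, sex-linked and unnamed predicted genes were left out of the largest changes. How reads shared by near-identical genes were counted is not given in the sources used here, so values within families such as the granzyme, Ly6, Gbp, H2, Hspa1, histone and haemoglobin genes are uncertain between copies.

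The tests were checked on simulated counts, with 200 changed genes for the gene tests and the interaction, 1 changed list for the gene lists and 3 changed classes of 13 for cell numbers. In simulated CD8 T-like cells, 68% of 2-fold and 97.9% of 4-fold changes were recovered, with 13 false calls of 175 among 10832 genes. The shares were 40.4% and 83.5% in simulated regulatory T-like cells (4 false of 118, 5670 genes), 74.7% and 91.9% in simulated macrophage-like cells (8 false of 173, 11442 genes), and 41% and 89% for the interaction (4 false of 134, 9779 genes). The changed list was called in each of the 3 simulated classes, with 0 false calls. Simulated genes were drawn independently of each other, so this cannot show false list calls that arise from correlated genes. For cell numbers, 77% of 4-fold changes were recovered and 1.67% of the unchanged classes tested were called falsely. These numbers were drawn at a fixed dispersion, and a fall in the changed classes did not raise the others. False calls that arise when a large class shifts the shares of the rest can therefore not be seen here.

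The alternatives were RLE factors (the size factors of DESeq2) within edgeR, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, and a stricter cell filter of 1000 genes and 5% mitochondrial UMIs. Others were doublets kept, doubled resolution, a per-cell gate for T cells, other thinning depths, and leaving out each library in turn. Further alternatives were chosen after the data were seen and are named in the closing section. Free RNA in droplets was approximated from each library's whole profile, since empty droplets were not analysed here. Figures were drawn with matplotlib 3.10.9.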

Results

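Transcripts were counted in single live CD45+ cells, the leukocytes, sorted from subcutaneous tumours of B16-F10, a mouse melanoma line. Mice had received isotype control antibody or a triple combination of antibodies on days 10, 13 and 16 after implantation, and tumours were taken on day 21. The triple combination was directed at PD-1, an inhibitory receptor of T cells, and at 4-1BB and OX40, costimulatory receptors of the TNF receptor family. Each group had 2 libraries. Isotype replicates 1 and 2 held 65233668 and 35537768 UMIs in 6514 and 3796 barcodes, and triple replicates 1 and 2 held 57702270 and 81797582 UMIs in 5638 and 6873 barcodes. After filtering, 6143, 3644, 5345 and 6444 cells remained. The labels do not say that the libraries came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

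The first comparison asked how the leukocyte make-up of the tumours differed under triple therapy. Dendritic cells and regulatory T cells made up a smaller part of the CD45+ cells. The share of mature DC-like cells, which carry antigen to lymph nodes, was 1.92 ± 0.116% in the isotype and 0.196 ± 0.0138% in the triple libraries (SD, n = 2 each; log2 ratio −3.28, SE 0.47, adjusted p = 0.00228). The share of pDC-like cells, known as producers of type I interferon, was 1.33 ± 0.103% against 0.159 ± 0.0929% (log2 ratio −3.06, SE 0.57, adjusted p = 0.0053). Regulatory T-like cells, which restrain immune responses, made up 2.72 ± 0.778% against 0.691 ± 0.0551% (log2 ratio −1.97, SE 0.46, adjusted p = 0.0134), but did not pass without triple replicate 1 (adjusted p = 0.144) or 2 (0.126). The cDC1-like share was 1.46 ± 0.324% against 0.521 ± 0.0567%, and the cDC2-like share was 4.44 ± 0.462% against 1.53 ± 0.338% (adjusted p = 0.0248 for each). Neither passed without isotype replicate 1, triple replicate 1 or triple replicate 2, with adjusted p = 0.115, 0.215 and 0.192 for cDC1-like and 0.0788, 0.24 and 0.126 for cDC2-like cells, nor with the replicate block (0.101 and 0.0863), and the pDC-like share did not pass without triple replicate 2 (0.0792). CD4 conventional T-like cells rose from 0.219 ± 0.195% to 1.17 ± 0.73% (log2 ratio 2.49, SE 0.79, adjusted p = 0.0265). Their log2 ratio was 1.70 without isotype replicate 1 and 1.65 without triple replicate 1 (adjusted p = 0.0788 and 0.215), and the rise did not pass with doublets kept (0.0843) or the stricter cell filter (0.0573) either. A per-cell gate put 0.488% and 1.34% of the isotype and 1.48% and 0.481% of the triple cells in this class, so the groups overlapped. B-like cells fell (log2 ratio −2.90, adjusted p = 0.0248), but 138 of the 173 B-like cells of the isotype group came from replicate 2, and without it the log2 ratio was −0.99. The fall did not pass with the stricter cell filter (adjusted p = 0.0953) or doublets kept (0.0835) either.

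CD8 T-like cells made up 11.0% and 18.4% of the isotype libraries and 46.2% and 24.2% of the triple libraries, a difference that did not pass (log2 ratio 1.26, SE 0.51, adjusted p = 0.0567). With B-like cells and the T cluster led by Lef1 and Satb1 left out, an alternative chosen after the data were seen, the log2 ratio was 1.79 with an adjusted p of 0.00216. Neutrophil-like (adjusted p = 0.0536), macrophage-like (0.157), NK-like (0.205) and monocyte-like shares (0.632) did not pass either. Under single alternatives some of these were called, namely lower neutrophil-like shares with the stricter cell filter (0.0155), doublets kept (0.0455) and B-like cells and the cluster led by Lef1 and Satb1 left out (0.0234). The macrophage-like share was called lower with the stricter cell filter (log2 ratio −1.22, adjusted p = 0.0289) and the monocyte-like share lower with doublets kept (−1.52, 0.0229). For the CD8 T-like share the log2 ratio was 1.68 without isotype replicate 2 and 1.65 without triple replicate 2. It was 0.93 without isotype replicate 1 and 0.72 without triple replicate 1. In all, 7 of the 12 classes passed with edgeR, and the exact permutation p was 0.333 for each of the 7. With TMM factors taken over the classes 0 passed, with adjusted p = 0.0567 for mature DC-like, CD4 and CD8 T-like cells. The log2 ratio was then −0.93 for regulatory T-like (adjusted p = 0.279), −0.46 for cDC1-like (0.629) and −0.57 for cDC2-like cells (0.455). DESeq2 on cell numbers also called 7. Without isotype replicate 1, triple replicate 1 or triple replicate 2, 4, 2 and 3 classes passed, and the mature DC-like share was among them each time. Some clusters stayed unnamed. A cluster led by Mmp12 and Adm held 11.7% and 9.63% of the isotype and 3.39% and 6.83% of the triple libraries. Its best score was for macrophages, so the macrophage-like share may leave out macrophages. A cluster with transcripts of both T cells and macrophages held 0.0977% and 0.0274% against 3.55% and 6.36%. A small T cluster held 0.0163% and 0% against 0.168% and 0.326%.

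**Figure D1:**
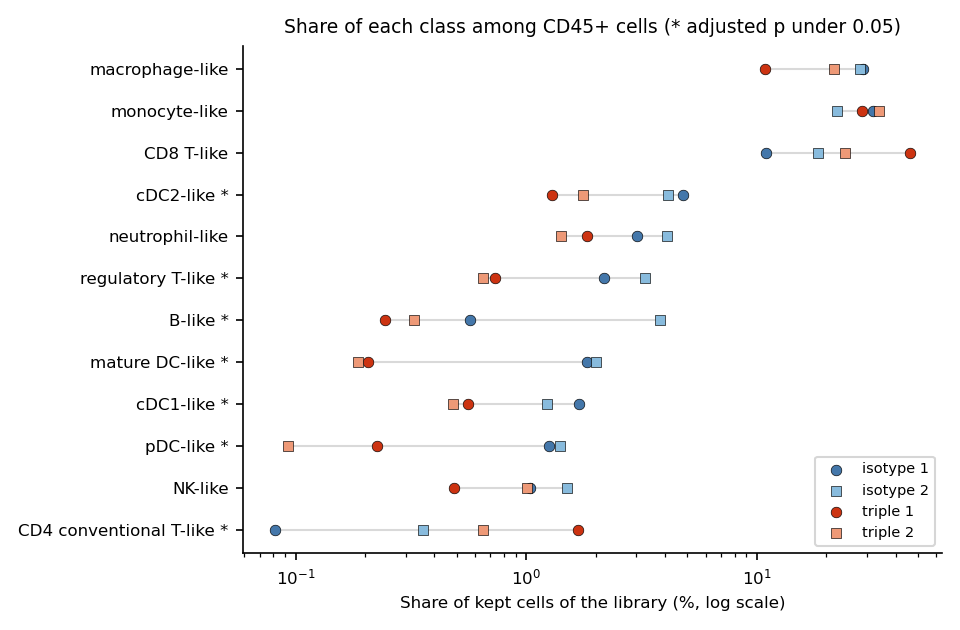
Share of each class among the kept CD45+ cells of each library, in percent on a log axis, with 1 point per library and a grey line over the range. Mature DC-like cells lay at 1.84% and 2.00% in the isotype and at 0.206% and 0.186% in the triple libraries.

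The genes of the 3 antibody targets were examined next. Tnfrsf4 encodes OX40 and lies at 156013843 to 156016612 on chromosome 4 (ENSMUSG00000029075). In CD8 T-like cells it fell from 404 ± 9.48 to 215 ± 28.4 CPM (TMM-scaled, SD, n = 2 each; log2 fold change −0.91, SE 0.13, adjusted p = 0.00892). Pdcd1, the gene of PD-1, had 523 ± 51.3 CPM in the isotype and 509 ± 36.4 CPM in the triple libraries (log2 fold change −0.04, adjusted p = 0.889). Tnfrsf9, the gene of 4-1BB, had 846 ± 116 and 841 ± 11.1 CPM (−0.01, adjusted p = 0.982), and leaving out single libraries turned the sign of both values. In regulatory T-like cells none of the 3 passed, with log2 fold changes of 0.17 for Pdcd1, −0.72 for Tnfrsf4 and 0.09 for Tnfrsf9 (adjusted p = 0.868, 0.113 and 0.946). Over all CD45+ cells, and without scaling, Pdcd1 was at 83.8 and 105 CPM in the isotype and 265 and 132 CPM in the triple libraries, Tnfrsf9 at 171 and 199 against 438 and 258 CPM, and Tnfrsf4 at 104 and 138 against 109 and 73.8 CPM, where the groups overlapped.

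The series title names functional, migratory and stem-like properties of CD8 T cells, and the gene comparison within CD8 T-like cells addressed these. Ccr2, a chemokine receptor that draws leukocytes into inflamed tissue (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), rose from 12.1 ± 3.48 to 92.7 ± 4.86 CPM (SD, n = 2 each; log2 fold change 2.92, SE 0.18, adjusted p = 0.000391). Gzma, which encodes granzyme A (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), rose from 55.1 ± 26.3 to 498 ± 123 CPM (log2 fold change 3.17, SE 0.30, adjusted p = 0.00207). Ccr7, the receptor that guides T cells to lymph nodes (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), fell from 584 ± 137 to 76.7 ± 0.561 CPM (log2 fold change −2.93, SE 0.17, adjusted p = 0.000385). Other large rises, between 1.86 and 1.38 on the log2 scale, were those of the interferon-induced GTPase genes Gbp2, Irgm1 and Igtp, the effector marker Klrg1, the granzyme gene Gzmk, the Ly6 family genes Ly6c2 and Ly6a, and Ifitm1, Phlda1 and Bcl3. Klf2, a transcription factor of T cells that leave tissues, fell by 2.09 on the log2 scale (SE 0.39, adjusted p = 0.0282), and Ramp3, Bmyc, Ddit4, Nrn1, Apoe, C1qtnf6, Rab3ip, Actn1 and Penk fell by between 1.92 and 1.14. The heat shock gene Hspa1a fell from 74.5 ± 30.9 to 35.0 ± 3.69 CPM (adjusted p = 0.0497). Apoe is a macrophage transcript, and 75.5% and 62.8% of CD8 T-like cells in the isotype and 72.0% and 86.2% in the triple libraries had a UMI of the macrophage genes C1qa, C1qb or C1qc.

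In total 309 of 10986 genes passed in CD8 T-like cells, 172 higher and 137 lower (edgeR quasi-likelihood, Benjamini-Hochberg). Isotype replicates 1 and 2 had 45.8% of their CD8 T-like cells in T cluster 3 and 47.8% in T cluster 5, the cluster led by Lef1 and Satb1, while T clusters 0 and 1 held 31.1% and 24.8% in triple replicate 1 and 16.9% and 20.2% in triple replicate 2. T cluster 5 held 17.5% of isotype replicate 1 and 0.405% and 0.321% of the triple libraries. Leaving it out, a step chosen after the data were seen, gave 713 genes, of which 284 were among the 309. Without isotype replicate 1, isotype replicate 2 or triple replicate 1, 930, 598 and 135 genes passed. Of the 52 called genes named in the class, 14 no longer passed without triple replicate 1 and 7 without triple replicate 2, and Klf2 was among both (adjusted p = 0.0971 and 0.0602).

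**Figure D2:**
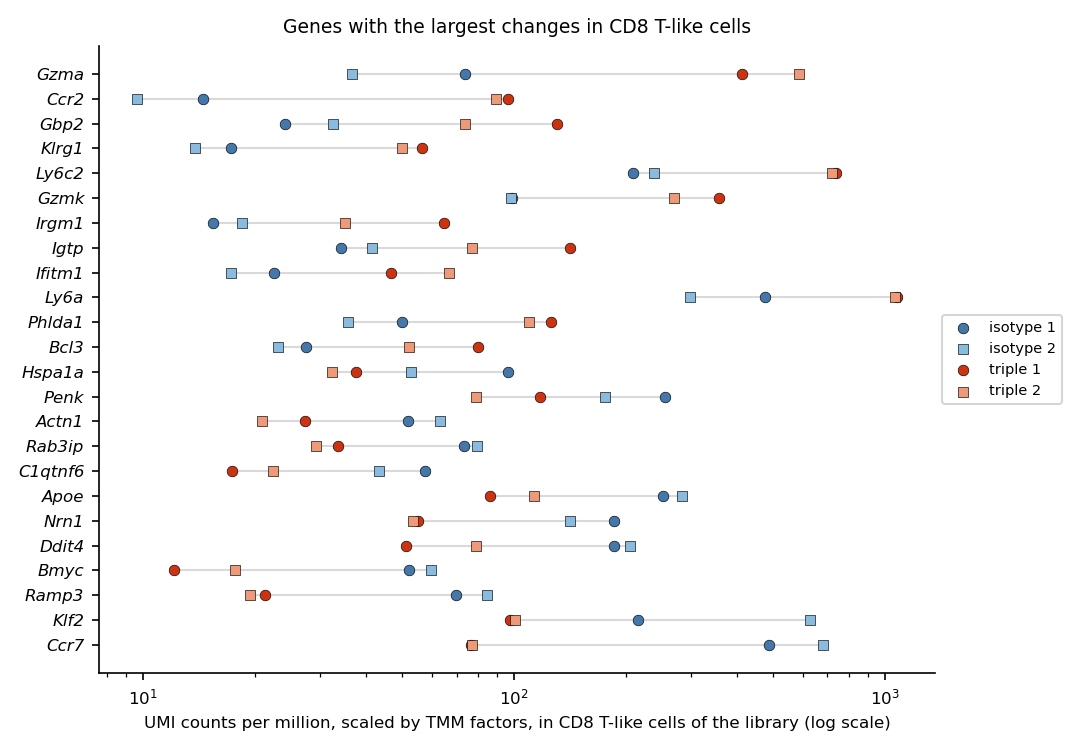
Levels in CPM in CD8 T-like cells on a log axis for the 12 genes with the largest rise and the 12 with the largest fall, with 1 point per library and a grey line over the range. Ccr2 lay at 12.1 ± 3.48 CPM in the isotype and 92.7 ± 4.86 CPM in the triple libraries.

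Fixed gene lists were then compared within CD8 T-like cells. Genes of the interferon gamma response rose together, with 13 of 17 measured members higher, 0 lower and 17 higher when adjusted over the list alone (median log2 fold change 1.36, camera adjusted p = 9.76e-17, adjusted p = 0.586 with an estimated correlation). Cxcl10, a chemokine for CXCR3-bearing cells (1.91), Gbp4 (1.29) and Irf1, a transcription factor of this response (1.19), were examples. In the cytotoxic effector list 5 of 17 members rose, namely Klrg1, Gzmk, Gzma, Gzmb and Nkg7, and adjusted over the list alone 9 rose and 3 fell (median 0.33, adjusted p = 0.000173, adjusted p = 0.586 with an estimated correlation). Of the T helper 1 list, 5 of 11 rose, among them Cxcr3 (1.82), a receptor for homing to inflamed tissue, and Il12rb1 (1.13), and 7 rose adjusted over the list alone (median 0.80, adjusted p = 0.00011, adjusted p = 0.586 with an estimated correlation). Effector cytokines and chemokines had Tnf (1.41) and Ccl5 (1.27) higher and Csf1 (−1.09) lower among 11 members, with 5 higher and 1 lower adjusted over the list alone (median 0.86, adjusted p = 0.00925, adjusted p = 0.586 with an estimated correlation). NF-kB targets had 3 of 15 members higher, Nfkbid (1.11), Nfkbia (0.72) and Nfkb1 (0.66), and 9 adjusted over the list alone (median 0.45, adjusted p = 0.00011, adjusted p = 0.586 with an estimated correlation). Of the type I interferon response 2 of 19 members rose, Zbp1 (1.33) and Ifi27l2a (1.01), with 5 adjusted over the list alone (median 0.39, adjusted p = 0.000176, adjusted p = 0.586 with an estimated correlation), and the list did not pass without isotype replicate 1 (adjusted p = 0.824). The stem-like and memory list was lower, with Ccr7 as the only called member of 14 and 4 lower adjusted over the list alone (median −0.75, adjusted p = 0.00505, adjusted p = 0.586 with an estimated correlation). Its median was 0.38 with an adjusted p of 0.111 when the cluster led by Lef1 and Satb1 was left out.

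Of the further lists that passed, the next 4 had 0 members called by edgeR over all genes, each with adjusted p = 0.586 with an estimated correlation. The medians were 0.30 for MHC class I presentation (14 members, 8 with an unadjusted p under 0.05 and 7 higher adjusted over the list alone, adjusted p = 4.7e-05), 0.20 for oxidative phosphorylation (18 members, 5 under 0.05 unadjusted, adjusted p = 0.000264) and 0.15 for proliferation (19 members, 4 under 0.05 unadjusted and 2 adjusted over the list alone, adjusted p = 0.00152). For MHC class II presentation the median was 0.32 (7 members, 4 under 0.05 unadjusted and 3 adjusted over the list alone, adjusted p = 0.00381), and −1.36 with free RNA subtracted. Lists of foreign transcripts passed higher as well (adjusted p = 0.00925 for each, adjusted p = 0.586 with an estimated correlation). Macrophage and monocyte transcripts had a median of 0.39, yet the only called member of 13, Apoe (−1.43), was lower, and adjusted over the list alone 4 rose and 1 fell. This list did not pass without isotype replicate 2 (adjusted p = 0.141), without triple replicate 2 (0.41) or with free RNA subtracted (0.393). Melanoma transcripts had a median of 1.01 with 0 of 6 called, 0 adjusted over the list alone and 2 under 0.05 unadjusted, and did not pass without isotype replicate 1 (0.0561) or 2 (0.0992). Free RNA was estimated at 2.28% and 2.26% of the UMIs of CD8 T-like cells in the isotype and 4.43% and 4.40% in the triple libraries. In all 13 of 23 lists passed, and each of the 13 had an adjusted p = 0.586 with an estimated correlation. With the cluster led by Lef1 and Satb1 left out, 10 of the 13 still passed in the same direction, 2 no longer passed and 1 turned direction. Without isotype replicate 2, 8 lists passed, and the stem-like list was not among them (adjusted p = 0.16). The migration and egress list held 4 genes that rose (Ccr2, Ly6c2, Cxcr3, Itgb7) and 3 that fell (Ccr7, Klf2, Cx3cr1) among 17, and adjusted over the list alone 7 rose and 5 fell (median 0.07, adjusted p = 0.119). The lists of inhibitory receptors and exhaustion (median 0.21, adjusted p = 0.121), costimulatory TNF receptor family and ligands (−0.01, 0.464), tissue residency (−0.15, 0.289), hypoxia (−0.01, 0.187), dissociation and heat shock (−0.23, 0.195) and neutrophil transcripts (−0.97, 0.119) did not pass. Neither did effector transcription factors, for which the test leaned up and the median was −0.03, glycolysis, which leaned up with a median of −0.01, and regulatory T suppressive genes, which leaned down with a median of 0.10. Some of these lists did pass under alternatives. Without triple replicate 2, inhibitory receptors (adjusted p = 0.00132), effector transcription factors (0.0134) and migration (0.0169) were higher and hypoxia (0.00113) lower, and without isotype replicate 1 neutrophil transcripts were lower (4.61e-07). With no filter on low counts 18 of 26 lists passed, with the replicate block 15 of 23 and without isotype replicate 1 16 of 24.

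**Figure D3:**
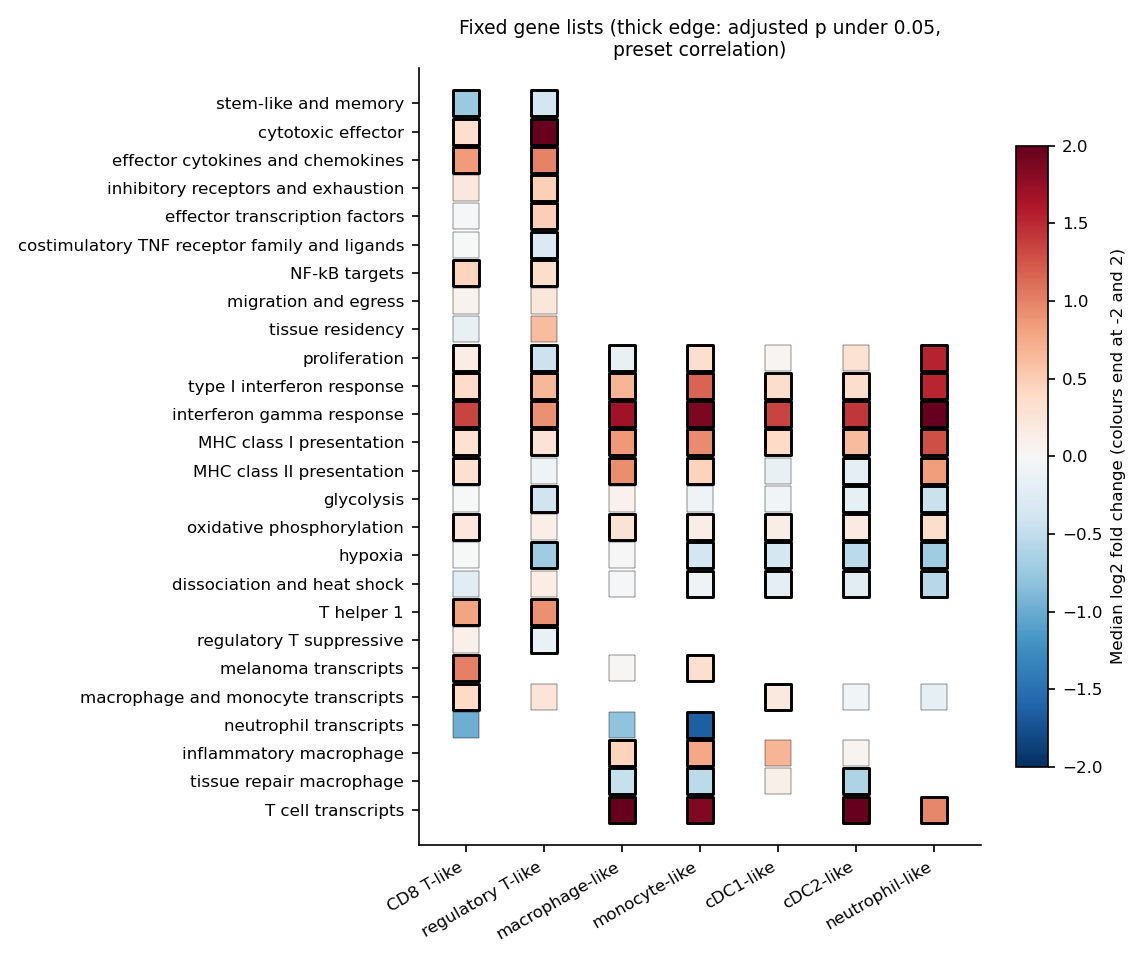
Median log2 fold change (triple minus isotype) of each fixed gene list in each class as a colour, with a thick edge where the adjusted p with the preset correlation was under 0.05. The interferon gamma response had medians from 0.91 in regulatory T-like to 2.16 in neutrophil-like cells, and with an estimated correlation 0 of the 108 lists passed.

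The make-up of CD8 T-like cells was compared in clusters built without the genes called in the class and without T cell receptor variable genes. State cluster 0, which matched no fixed state and was led by Gzma, Cxcr3 and Ccr2, held 3.56% and 2.98% of the isotype and 40.9% and 30.7% of the triple CD8 T-like cells (log2 ratio 3.45, SE 0.78, edgeR adjusted p = 0.00195). State cluster 4, which was stem-like by its markers, held 17.5% and 48.1% against 0.81% and 1.35% (log2 ratio −4.93, SE 0.83, adjusted p = 0.000247), and 323 of its 482 cells came from isotype replicate 2. A cycling cluster, number 5, rose from 1.04% and 0.893% to 7.33% and 11.2% (log2 ratio 3.25, SE 0.82, adjusted p = 0.00343). The exhausted clusters 1 (log2 ratio −0.25, adjusted p = 0.846) and 3 (−0.29, 0.846), the cycling cluster 2 (0.00, 0.996) and the interferon cluster 6 (−1.19, 0.238) did not pass. The exact permutation p of the 3 that passed was 0.333. Without either triple library 0 of 6 clusters passed with edgeR, with 2 at an unadjusted p under 0.05 each time. With the T cluster led by Lef1 and Satb1 left out, the stem-like cluster held 0.36% and 1.42% against 0.447% and 1.09% of cells (log2 ratio −0.13, adjusted p = 0.889).

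**Figure D4:**
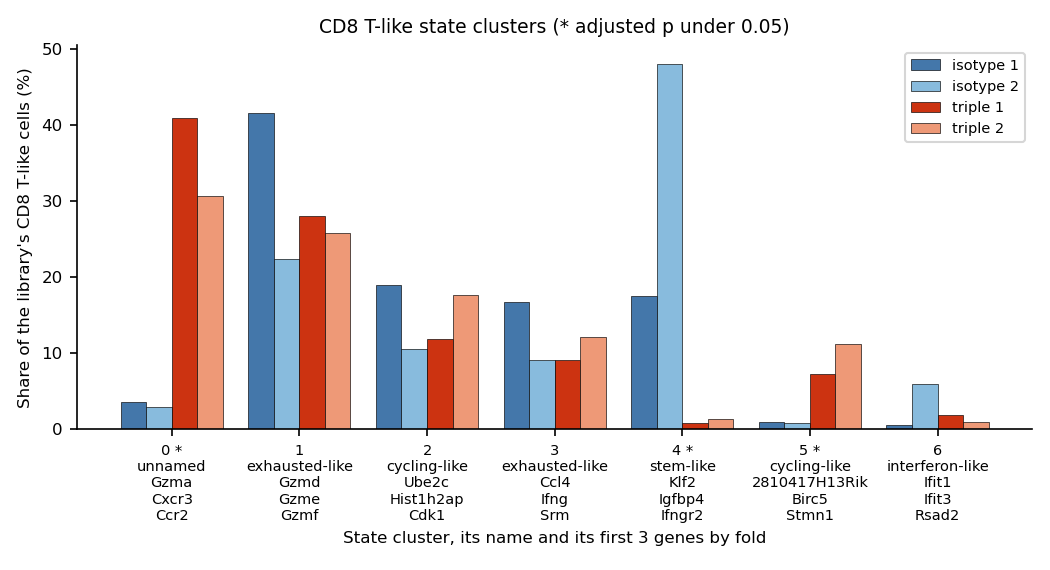
Share of each state cluster among the CD8 T-like cells of each library, in percent, with 1 bar per library and the first 3 genes of each cluster by fold under its number. State cluster 0 held 3.56% and 2.98% of the isotype and 40.9% and 30.7% of the triple cells.

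Shares of CD8 T-like cells with a UMI of single genes were compared after thinning each cell to 1000 UMIs. Gzmb, the granzyme B gene, was detected in 48.4% and 26.5% of isotype and 61.2% and 66.8% of triple cells, against 1.12%, 0.982%, 5.88% and 6.04% in macrophage-like cells as background. Klrg1 was detected in 0.89% and 0.744% against 4.90% and 5.33% (background 0.112%, 0%, 0.173% and 0.216%, where 0 of 1018 cells has an upper bound of 0.376%), and Cxcr3 in 1.93% and 2.08% against 7.09% and 5.84% (background 0.169%, 0.295%, 0.173% and 0.144%). Tnfrsf4 was detected in 24.6% and 17.9% against 11.8% and 14.1% (background 0.843%, 1.18%, 1.04% and 0.863%). Tcf7, a transcription factor of stem-like T cells, was detected in 3.56% and 10.4% against 2.63% and 2.18% (background 0.0562%, 0.295%, 0.173% and 0.0719%). With the cluster led by Lef1 and Satb1 left out, these shares were 0.899% and 1.42% against 2.64% and 2.19%. That cluster held 17.5% and 47.8% of isotype and 0.405% and 0.321% of triple CD8 T-like cells. Over all share comparisons run, leaving it out moved 11 differences, reversed 1 and left 5 the same. Cells with both Tcf7 and Pdcd1 numbered 3, 1, 8 and 6 in the 4 libraries, and their shares of 0.445% and 0.149% in the isotype and 0.324% and 0.385% in the triple libraries overlapped. Before thinning, the shares were 72.6%, 42.4%, 89.7% and 92.2% for Gzmb, 10.4%, 6.4%, 25.5% and 25.9% for Klrg1, 7.27%, 6.99%, 29.8% and 23.5% for Cxcr3, 65.9%, 42.4%, 42.5% and 45.3% for Tnfrsf4, which then overlapped, and 12.9%, 28.1%, 12.3% and 11.7% for Tcf7. The exact permutation p was 0.333 wherever the groups did not overlap. Median UMIs per CD8 T-like cell were 8189.5 and 4563.5 in the isotype and 7028 and 7455.5 in the triple libraries, so shares before thinning were taken at unequal depth, and per macrophage-like cell they were 12070 and 11913 against 13539.5 and 15367.

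Regulatory T-like cells were examined in the same way. Transcripts typical of CD8 and NK cells were higher in them, and Ctla4, an inhibitory receptor on which their suppression depends, fell (log2 fold change −1.37, SE 0.19, adjusted p = 0.000352). Cd8a rose from 18.1 ± 1.97 to 310 ± 60.5 CPM (SD, n = 2 each; log2 fold change 4.07, SE 0.27, adjusted p = 1.11e-07), and Klrd1, Klrk1 and Klrc1, receptors of NK and cytotoxic T cells, rose by 4.17, 4.56 and 3.42. Gzmk had 146 ± 41.2 CPM in the triple libraries and 1 UMI over both isotype libraries. Ly6c2 (4.74) and Nrgn (5.10) also rose. Ccr7 (−2.26), Ddit4 (−2.16) and Ndrg1 (−1.93), of which the last pair respond to hypoxia, fell, as did S100a8 (−1.95), a neutrophil transcript, and the histone genes Hist1h2bj (−2.25) and Hist1h1b (−1.85). The cells with 5 or more UMIs of Cd8a and Cd8b1 numbered 3 and 1 in the isotype and 13 and 20 in the triple libraries, out of 133, 119, 39 and 42. Their RNA is part of the class sums. Ctla4 and the list of suppressive genes were not compared without them, so a fall in either cannot be assigned to regulatory T cells alone.

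In this class 77 of 5986 genes passed, 57 higher and 20 lower (edgeR quasi-likelihood, Benjamini-Hochberg), and without triple replicate 2 there were 209. DESeq2 called 44. Of the cytotoxic effector list 11 of 17 members rose, 14 adjusted over the list alone (median 2.46, camera adjusted p = 1.7e-21, adjusted p = 0.38 with an estimated correlation). From plain CPM its median was 2.41, and 1.03 in cells without a Cd8a or Cd8b1 UMI, which numbered 13 and 10 in the triple libraries and in which 12 of the 17 genes had at most 5 UMIs in each of them. Of the hypoxia list 2 of 10 fell, 4 adjusted over the list alone (median −0.71, adjusted p = 3.5e-06, adjusted p = 0.38 with an estimated correlation). The interferon gamma response had Socs1 (1.30) and Iigp1 (1.42) higher among 14 members, 10 adjusted over the list alone, with a median of 0.91 and an adjusted p of 1.95e-10 (adjusted p = 0.403 with an estimated correlation). T helper 1 genes (median 0.91, 3 of 11 higher, 4 over the list alone), effector cytokines and chemokines (0.99, 2 of 7, 3 over the list alone), and inhibitory receptors and exhaustion (0.47, with Nr4a2, Cd160 and Rgs16 higher and Ctla4 lower among 12) also passed, each with adjusted p = 0.403 with an estimated correlation. So did glycolysis (−0.39, with Slc16a3 lower among 16), stem-like and memory genes (−0.36, with Ccr7 and Il7r lower among 12) and regulatory T suppressive genes (−0.13, with Ctla4 lower among 16). Proliferation (median −0.43, camera adjusted p = 5.8e-07) and costimulatory TNF receptor family and ligands (−0.29, 0.00701) passed lower with 0 members called. The type I interferon response (0.66, 1.17e-05), NF-kB targets (0.35, 0.00313), MHC class I presentation (0.28, 0.00313) and effector transcription factors (0.49, 0.00597) passed higher with 0 called. With an estimated correlation glycolysis, the stem-like list, proliferation and the type I interferon response had an adjusted p = 0.403. The suppressive list and the other lists without called members had an adjusted p = 0.431, and for none of the 15 of 21 lists that passed was it lower than 0.38. Without triple replicate 2 the suppressive list no longer passed (adjusted p = 0.35). Most regulatory T-like cells lay in T cluster 8, with 71.4% and 53.8% in the isotype and 94.9% and 76.2% in the triple libraries.

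The treatment effect was compared between CD8 T-like and regulatory T-like cells with an interaction test. It differed for 185 of 10021 genes, of which 78 had a higher log2 effect in CD8 T-like cells and 107 a lower one (edgeR quasi-likelihood, Benjamini-Hochberg). The Ccr2 effect was higher in CD8 T-like cells by 3.42 (SE 0.22), and the Cd8a effect was lower by a log2 difference of −3.91 (SE 0.23). Effects of Cd8b1, Klrd1, Klrk1 and Gzmk were lower too. In the regulatory T-like class, 33.3% and 47.6% of triple cells had 5 or more Cd8a and Cd8b1 UMIs, against 2.3% and 0.8% of isotype cells. The interaction was not run without such cells, so these differences cannot be assigned to regulatory T cells. Without isotype replicate 1 or 2 the count was 100 or 101. The fit leaves few degrees of freedom per gene, so its p-values lean on a dispersion shared over genes.

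Macrophage-like cells were compared next. Nos2, the inducible nitric oxide synthase of inflammatory macrophages, rose from 9.35 ± 5.64 to 80.5 ± 17.4 CPM (SD, n = 2 each; log2 fold change 3.04, SE 0.32, adjusted p = 0.00176), and Upp1, a uridine phosphorylase gene, from 13.3 ± 0.766 to 113 ± 27.8 CPM (3.09, SE 0.17, adjusted p = 0.000197). Ly6i (3.23), Cnn3 (2.64) and Ly6a (2.62) rose as well. Apoe, a lipid carrier, fell by 1.77 on the log2 scale (SE 0.14, adjusted p = 0.000636), and Gas6, a ligand that aids the uptake of dying cells, fell from 71.6 ± 6.91 to 21.3 ± 1.51 CPM (−1.76, SE 0.11, adjusted p = 0.000261). Saa3 (−2.47), Trf (−1.90), Ccl24 (−1.73) and Ppbp (−1.73) also fell. All 18 measured members of the interferon gamma response rose, among them Gbp4 (2.44), Gbp5 (1.85) and Cd274, the gene of the PD-1 ligand (1.11), with a median of 1.69 and a camera adjusted p of 5.04e-18 (adjusted p = 0.257 with an estimated correlation). MHC class I presentation had 12 of 14 members higher and 14 adjusted over the list alone (median 0.87, adjusted p = 2.67e-15, adjusted p = 0.257 with an estimated correlation), with H2-Q7 (1.57) and Tap1 (1.03) as examples, and MHC class II presentation had 7 of 8 higher and 8 adjusted over the list alone (median 0.93, adjusted p = 2.71e-09, adjusted p = 0.257 with an estimated correlation), with H2-Ab1 (1.02) and Cd74 (0.93). Tissue repair genes fell, with 7 of 15 lower, 0 higher, and 9 lower and 1 higher adjusted over the list alone (median −0.46, adjusted p = 1.6e-05, adjusted p = 0.257 with an estimated correlation), among them Fn1 (−1.07), Mrc1 (−0.94) and Spp1 (−0.86).

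The inflammatory macrophage list had 6 of 14 members higher (median 0.46, adjusted p = 0.000105, but 0.057 without triple replicate 1), and the type I interferon list 12 of 20, 16 adjusted over the list alone (median 0.69, adjusted p = 7.7e-10), each with adjusted p = 0.257 with an estimated correlation. Within macrophage-like clusters 5, 6, 7 and 17, a comparison chosen after the results were seen, the type I list had medians of 0.40, 1.08, −0.14 and 0.05. Oxidative phosphorylation had 5 of 18 higher, 14 adjusted over the list alone (median 0.29, adjusted p = 3.13e-07, adjusted p = 0.257 with an estimated correlation). Proliferation had Mki67 (−0.66) lower among 19 (median −0.14, adjusted p = 0.0451), and did not pass without isotype replicate 1 (adjusted p = 0.254) or triple replicate 1 (0.813). With an estimated correlation its adjusted p was 0.695. Transcripts of T cells moved with these groups. All 6 measured members of the T cell list rose in macrophage-like cells (median 2.17, adjusted p = 2.71e-10, adjusted p = 0.257 with an estimated correlation), and its adjusted p was 0.412 with free RNA subtracted. A Cd3 UMI was found in 21.0% and 24.4% of isotype and 73.9% and 68.1% of triple macrophage-like cells. Erythrocyte transcripts moved the other way, with all 4 measured haemoglobin genes lower, such as Hbb-bs (−3.11, SE 0.41, adjusted p = 0.00412) and Hba-a1 (−3.25, SE 0.47, adjusted p = 0.00633). Nkg7 (2.90), a cytotoxic lymphocyte transcript, Pdcd1 (1.81, adjusted p = 0.00205) and Tnfrsf9 (1.07, adjusted p = 0.00389) rose beside the T cell genes, and Tnfrsf9 had a log2 fold change of −1.18 with free RNA subtracted. Free RNA was estimated at 4.45% and 4.76% of UMIs in the isotype and 6.16% and 11.6% in the triple libraries.

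In macrophage-like cells 1068 of 11576 genes passed, 679 higher and 389 lower (edgeR quasi-likelihood, Benjamini-Hochberg). Without triple replicate 1 or 2 the count was 685 or 325, and Saa3 no longer passed (adjusted p = 0.0842 and 0.253). Cluster 5 held 35.8% and 37.9% of the isotype and 11.9% and 8.34% of the triple macrophage-like cells, and cluster 8 held 4.05% and 2.16% against 38.2% and 43.4%. Glycolysis (median 0.08, adjusted p = 0.0601), hypoxia (0.01, with the test leaning down, 0.909), dissociation and heat shock (−0.02, 0.909), melanoma transcripts (0.02, 0.909) and neutrophil transcripts (−0.80, 0.223) did not pass. The unnamed cluster led by Mmp12 and Adm scored best for macrophages but was not part of this class. Adm, Egln3, Ero1l and Ndrg1 of the hypoxia list were among its leading genes. It held 11.7% and 9.63% of the isotype and 3.39% and 6.83% of the triple libraries. The hypoxia result therefore covers only the named macrophage-like cells.

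Monocyte-like cells showed changes in many of the same gene groups. Iigp1, an interferon-inducible GTPase gene, rose from 13.9 ± 0.474 to 283 ± 6.92 CPM (SD, n = 2 each; log2 fold change 4.34, SE 0.11, adjusted p = 6.55e-07), Nos2 rose by 3.17 (SE 0.12, adjusted p = 7.53e-06), and the chemokine gene Ccl8 by 2.81 (SE 0.16). Ly6i (2.75), Upp1 (2.74) and Batf2 (2.74), an interferon-induced transcription factor, rose too. Retnla, a gene of alternatively activated macrophages, fell from 128 ± 8.85 to 10.2 ± 8.11 CPM (−3.72, SE 0.41, adjusted p = 0.000728), and Wfdc21 (−3.81), Lcn2 (−2.62), Apoe (−2.43), S100a8 (−2.27) and Chil3 (−2.19) fell. All 18 members of the interferon gamma response (median 1.89, adjusted p = 3.36e-22), all 14 of MHC class I presentation (median 0.94, adjusted p = 2.56e-16) and all 8 of MHC class II presentation (median 0.45, adjusted p = 1.63e-05) rose, each list with adjusted p = 0.233 with an estimated correlation. With doublets kept H2-Ab1 and H2-Aa had log2 fold changes of −0.0435 and −0.0563, and without isotype replicate 2 they did not pass (adjusted p = 0.118 and 0.191). Of the type I interferon response 17 of 20 rose, 18 adjusted over the list alone, with Isg15 (1.56) and Irf7 (1.29) among them (median 1.16, adjusted p = 2.2e-14, adjusted p = 0.233 with an estimated correlation). Within monocyte-like clusters 0, 2 and 10, also compared after the results were seen, its medians were −0.32, 0.30 and 0.63, and those of the interferon gamma response 0.11, 1.06 and 1.03. Inflammatory macrophage genes had 9 of 15 higher, 11 adjusted over the list alone, with Cxcl10 (1.85), Cxcl9 (1.46) and Cd40 (1.31) as examples (median 0.78, adjusted p = 1.61e-07, adjusted p = 0.233 with an estimated correlation). Tissue repair genes had 7 of 14 lower, among them Fn1 (−2.11), Mrc1 (−1.12) and Trem2 (−0.80), and 2 higher, with 7 lower and 3 higher adjusted over the list alone (median −0.54, adjusted p = 0.00166, adjusted p = 0.233 with an estimated correlation). Of the hypoxia list 3 of 12 fell, Ddit4 (−1.63), Mxi1 (−0.76) and Vegfa (−0.66), with 7 lower and 1 higher adjusted over the list alone (median −0.37, adjusted p = 0.00278, adjusted p = 0.26 with an estimated correlation).

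Neutrophil transcripts (median −1.64, 3 of 6 lower, 4 lower and 1 higher adjusted over the list alone) and T cell transcripts (median 1.86, 6 of 6 higher) moved with these groups (adjusted p = 0.00343 and 5.1e-07, adjusted p = 0.233 with an estimated correlation), and a Cd3 UMI was found in 15% and 18.2% of isotype and 60.9% and 49.7% of triple monocyte-like cells. Pdcd1 rose in them by 1.91 (adjusted p = 0.00124). Proliferation (median 0.33, with Stmn1, Ube2c, Birc5 and Ccna2 higher among 19, 6 adjusted over the list alone), melanoma transcripts (0.33, with Gpnmb higher among 7), oxidative phosphorylation (0.14, 3 of 18 higher) and dissociation and heat shock (−0.09, with Egr1 higher and 4 of 17 lower, 5 adjusted over the list alone) passed with adjusted p = 0.00375, 0.029, 0.0075 and 0.0241, the first 3 with adjusted p = 0.233 and the last with adjusted p = 0.469 with an estimated correlation. Egr1 was at −0.17 and Gpnmb at −0.82 with doublets kept. Another alternative pooled the monocyte and macrophage classes together with the unnamed cluster led by Mmp12 and Adm. There Stmn1 was at −0.29, Birc5 at −0.19, Ccna2 at −0.36 and Gpnmb at −0.50. Proliferation and melanoma transcripts had medians of −0.26 and −0.53 with free RNA subtracted, and dissociation and heat shock did not pass without isotype replicate 1 (adjusted p = 0.289) or triple replicate 2 (0.144). Melanoma transcripts did not pass without isotype replicate 1 (0.242), isotype replicate 2 (0.0632) or triple replicate 2 (0.113), and oxidative phosphorylation did not without triple replicate 2 (0.0523). Glycolysis was the list that did not pass (median −0.09, adjusted p = 0.605). In total 1664 of 10723 genes passed, 917 higher and 747 lower (edgeR quasi-likelihood, Benjamini-Hochberg), and 771 without isotype replicate 2. DESeq2 called 1106. Cluster 2 held 58.2% and 51.1% of the isotype and 8.59% and 6.72% of the triple monocyte-like cells, cluster 11 held 24.3% and 34.7% against 1.05% and 1.00%, and cluster 0 held 8.71% and 6.32% against 55.4% and 58.0%.

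**Figure D5:**
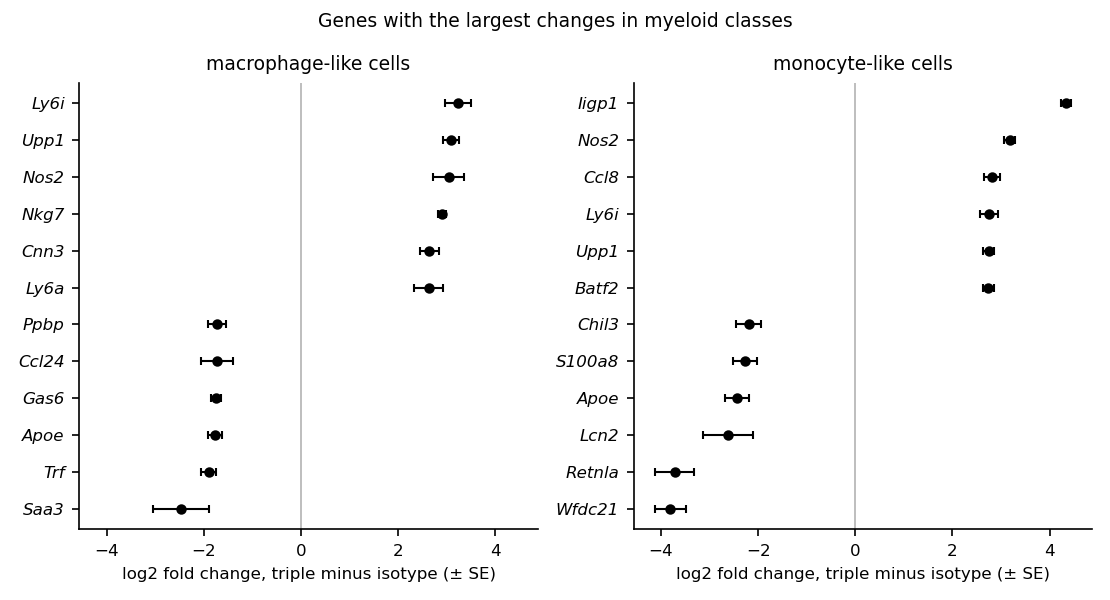
Log2 fold change (triple minus isotype) of the 6 genes with the largest rise and the 6 with the largest fall in macrophage-like cells (left) and monocyte-like cells (right). Points are edgeR estimates and bars are 1 SE, and Nos2 stood at 3.04 and 3.17.

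Dendritic cells and neutrophils were compared last. In cDC2-like cells Iigp1 rose by 3.13 (SE 0.24, adjusted p = 0.000164), and Pgf, a growth factor of the VEGF family, fell from 91.3 ± 40.3 to 7.7 ± 3.82 CPM (SD, n = 2 each; log2 fold change −3.62, SE 0.44, adjusted p = 0.00102). Fn1 fell by 2.98, and Hspb1, a heat shock gene, had 152 ± 151 CPM in the isotype libraries and 1 UMI over both triple libraries. Tnfrsf4 (2.52, SE 0.34, adjusted p = 0.00158) and Tnfrsf9 (1.36, SE 0.25, adjusted p = 0.0107) rose in this class, the second with an adjusted p of 0.873 when free RNA was subtracted. Of the interferon gamma response, 13 of 17 members rose, 16 adjusted over the list alone (median 1.43, adjusted p = 2.73e-22, adjusted p = 0.303 with an estimated correlation), and MHC class I presentation 8 of 14, 12 adjusted over the list alone (median 0.64, adjusted p = 1.72e-13, adjusted p = 0.303 with an estimated correlation). MHC class II presentation fell, with Cd74 (−0.32) and H2-Aa (−0.43) lower among 8 and 4 adjusted over the list alone (median −0.19, adjusted p = 0.0024, adjusted p = 0.385 with an estimated correlation), and it did not pass with free RNA subtracted (adjusted p = 0.345). Dissociation and heat shock genes fell with them, Hspa1b (−2.11), Hspa1a (−1.24) and Hsp90aa1 (−0.58) among 17, and adjusted over the list alone 4 fell and 1 rose (median −0.23, adjusted p = 0.000201, adjusted p = 0.303 with an estimated correlation). T cell transcripts rose here too, with 5 of 6 higher and 6 adjusted over the list alone (median 2.46, adjusted p = 9.45e-13, adjusted p = 0.284 with an estimated correlation), Cd3g (3.14) and Nkg7 (3.07) among the largest changes, and a Cd3 UMI in 18.4% and 17.3% of isotype and 65.2% and 53.5% of triple cells. In all 245 of 7022 genes passed, 132 higher and 113 lower, and DESeq2 called 144.

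In cDC1-like cells Tnf rose by 3.43 (SE 0.36) and Ly6a by 2.80 (SE 0.28; adjusted p = 0.00415 for each), Ly6c2 (2.33) and Oasl1 (2.22) rose, and Ramp3 (−2.90), Il1r2 (−2.33), a decoy receptor for interleukin 1, and Khk (−1.82) fell. C1qa (1.66), a macrophage transcript, rose with them. The interferon gamma response had 3 of 13 members higher, 11 adjusted over the list alone (median 1.35, adjusted p = 1.08e-15, adjusted p = 0.415 with an estimated correlation). Dissociation and heat shock genes passed lower as a list with 0 of 17 members called by edgeR, 5 at an unadjusted p under 0.05, and 3 lower and 1 higher adjusted over the list alone (median −0.19, adjusted p = 0.0322, adjusted p = 0.415 with an estimated correlation). The list did not pass without isotype replicate 1 (adjusted p = 0.379) or triple replicate 1 (0.31). Of 5093 genes 45 passed, 26 higher and 19 lower. With edgeR 0 passed without triple replicate 1 or 2, where 549 and 519 had an unadjusted p under 0.05.

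In neutrophil-like cells Iigp1 (4.06, SE 0.44) and Ly6i (3.22, SE 0.35) rose with adjusted p = 0.00641, and Gbp5 rose from 10.8 ± 10.4 to 99.8 ± 9.19 CPM (adjusted p = 0.0399, and 0.161 without triple replicate 1). Haemoglobin genes, which are erythrocyte transcripts, were lower, with Hbb-bs at 4.25 ± 3.69 CPM in the triple libraries and a log2 fold change of −9.73 (SE 0.54, adjusted p = 6.98e-05). The interferon gamma response had 9 of 15 members higher, 14 adjusted over the list alone (median 2.16, adjusted p = 4.94e-21, adjusted p = 0.175 with an estimated correlation). T cell transcripts rose as a list with 0 of 6 called by edgeR, 3 at an unadjusted p under 0.05 and 2 higher adjusted over the list alone (median 0.98, adjusted p = 0.000279, adjusted p = 0.308 with an estimated correlation). The list did not pass without isotype replicate 1 (adjusted p = 0.156), and a Cd3 UMI was found in 19.4% and 31.1% of isotype and 70.4% and 56.0% of triple neutrophil-like cells. Dissociation and heat shock genes were lower, with Hspa1b (−1.75) called among 17 and 2 adjusted over the list alone (median −0.55, adjusted p = 1.34e-05, adjusted p = 0.193 with an estimated correlation). Of 4584 genes 36 passed, 27 higher and 9 lower. Leaving out single libraries gave 9 to 434, and with free RNA subtracted 0 of 3366 passed with edgeR, with 113 at an unadjusted p under 0.05. DESeq2 called 74 on the unsubtracted counts. Free RNA was estimated at 15.2% and 35.1% of the UMIs of neutrophil-like cells in the isotype and 21.0% and 40.2% in the triple libraries.

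Across the classes, 77 of 108 list tests passed with the preset correlation. With an estimated correlation 0 passed in camera, 4 had an unadjusted p under 0.05, and the lowest adjusted p was 0.175.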

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

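The tests of free RNA and of CD8 T cells as the only source for regulatory T-like cells were chosen after the result was seen, as was the demand that the Foxp3 ratio hold at equal depth, and the other tests named here were written down before their values were computed. The treatment effect differed between CD8 T-like and regulatory T-like cells for 185 genes, and these genes were looked at again because classes of the same libraries gave different answers. Ccr2 was higher by 3.42 in the CD8 T-like effect (log2 fold change 2.92 against −0.51). Nrgn differed by −5.86 (−0.71 against 5.10), Ccl9 by −3.31 (−0.72 against 2.59) and Plac8 by −2.15 (−0.29 against 1.82). A cluster with transcripts of T cells and macrophages, which belonged to no class, held a mean of 4.96% of the triple cells and was left out of the comparisons.

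T cell transcripts were higher in macrophage-like cells of the triple libraries. RNA of T cells, free or in mixed droplets, may account for it, since the T cell genes rose with the whole library and differed from the Cd3 genes by a median of −0.381 over 111 genes. Free RNA as the only source of the Cd3 UMIs was excluded by their spread over cells. Their variance was 4.77 and 6.38 times the mean in the triple libraries, where at most 2 was predicted. In the isotype libraries it was 3.27 and 2.9 times the mean, also above 2. The spread therefore cannot tell how much of the rise came from free RNA, and the T cell list did not pass with free RNA subtracted. Droplets holding a macrophage and a T cell alone cannot be told apart from a mixture of sources, because 33.7% of the Cd3 UMIs lay in cells with 5 or more, between the bounds of 20% and 50% set beforehand. Uptake of T cell material by macrophages under treatment was not tested and stays open.

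CD8 and cytotoxic transcripts were higher in regulatory T-like cells of the triple libraries. Assignment of CD8 T cells without Foxp3 to the class cannot be told apart from other sources: Foxp3 was found in 63.6% of the 33 cells with 5 or more UMIs of Cd8a and Cd8b1 and in 78.3% of the 23 with none, a ratio of 0.813 that passed the bound of 0.8 set beforehand, but the former cells had more UMIs, and at an equal depth of 2000 UMIs the ratio was 0.37 in one triple library and 0.99 in the other. Foxp3 was found in 53.8% and 70% of the former cells, which numbered 13 and 20 in the triple libraries. It was found in 1.15% and 3.88% of CD8 T-like cells of similar or greater depth, which passed the bound set against such cells as the only source. The class was formed and named by genes such as Foxp3, so a higher Foxp3 share in it is partly built in. This source alone therefore cannot be excluded. Free RNA alone was excluded, since Cd8a and Cd8b1 UMIs were 11.17 times as frequent as in NK-like cells. Droplets holding a CD8 T cell and a regulatory T cell may account for the rise, since the 33 cells had a median of 11804 UMIs against 4752, a ratio of 2.484. Medians were 9639 against 4290 in triple replicate 1 and 12582.5 against 8053.5 in triple replicate 2. Choosing cells with 5 or more such UMIs favours deep cells by itself, so the ratio cannot decide for these droplets. A cytotoxic programme in regulatory T cells under treatment was not tested and stays open.

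The cluster with T cell and macrophage transcripts was larger in the triple libraries. Random pairing in droplets at the same rate in all libraries was excluded as the only source. Barcodes rich in both, set against the product of the shares and the barcodes loaded, were 5.6 times as frequent in the triple as in the isotype group (3.68 to 10.16 over pairs of libraries). The isotype side rested on 39 and 5 such barcodes. Random pairs as a part of the cluster cannot be excluded by this ratio. The cluster stayed unnamed because of its mean doublet score of 0.1305. Its median UMIs in the triple libraries were 17309 and 15810.5, against 7028 and 7455.5 in CD8 T-like and 13539.5 and 15367 in macrophage-like cells. Free RNA alone was excluded, since the median Cd3 UMIs of its cells were 0.571 and 0.677 times those of CD8 T-like cells in the triple libraries. T cells attached to macrophages under treatment were not tested and stay open.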

How the results depend on the processing

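Several alternatives were chosen after the results were seen, namely free RNA subtracted, the T cluster led by Lef1 and Satb1 left out, that cluster and B-like cells left out, monocyte and macrophage classes pooled, NK-like cells at a minimum of 20 cells, and the crossed replicate block. The pool of monocyte and macrophage classes also held the unnamed cluster led by Mmp12 and Adm. Of the 254 named genes called, 134 stayed past the threshold in the same direction under each alternative run, and 246 kept their direction. Without triple replicate 1 or 2, 47 and 49 of the 254 no longer passed, without isotype replicate 2, 29, with DESeq2 28 of 250 and with free RNA subtracted 33 of 241. Of 31 gene lists run and not called, 20 were called under an alternative. A single library left in a group was assumed to vary like the other group. The main tests of CD4 conventional T-like and NK-like cells and the interaction of CD8 with CD4 cells were not run (fewer than 30 cells), and of their alternatives only the per-cell gate for CD4 cells and the minimum of 20 cells for NK-like cells were. Not run either was the stricter cell filter in cDC1-like cells, and the per-cell gate was used for T cells only. For results that did not hold, the cause was not tested.

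Leaving out single libraries gave 135 to 930 genes in CD8 T-like cells, 325 to 1188 in macrophage-like, 771 to 1677 in monocyte-like and 63 to 209 in regulatory T-like cells, and 100 to 175 for the interaction. It gave 2 to 7 classes, 8 to 16 gene lists in CD8 T-like cells and 0 to 4 state clusters. Log2 values ranged from −0.13 to 0.0895 for Pdcd1 and from −0.13 to 0.16 for Tnfrsf9 in CD8 T-like cells, and from −0.0146 to 0.35 for Pdcd1 and from −0.14 to 0.33 for Tnfrsf9 in regulatory T-like cells. The share of monocyte-like cells ranged from −0.0244 to 0.50. State clusters 1, 2, 3 and 6 ranged from −0.62 to 0.26, from −0.36 to 0.48, from −0.66 to 0.22 and from −2.03 to 1.28.

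With RLE factors, no filter on low counts and DESeq2, Tnfrsf9 in CD8 T-like cells had log2 values of 0.00687, 0.0204 and 0.0068. Without the filter 1152 genes passed in CD8 T-like, 1925 in macrophage-like and 144 in regulatory T-like cells. DESeq2 called 1106 genes in monocyte-like and 44 in regulatory T-like cells. With the stricter cell filter 670 passed in macrophage-like and 123 in regulatory T-like cells, and Tnfrsf9 had log2 values of 0.00274 in CD8 T-like and −0.0015 in regulatory T-like cells. With doublets kept 1964 genes passed in macrophage-like and 985 in monocyte-like cells, the monocyte-like share had a log2 ratio of −1.52, and in monocyte-like cells H2-Ab1 was at −0.0435, H2-Aa at −0.0563, Egr1 at −0.17 and Gpnmb at −0.82. With doubled resolution 7 of 13 CD8 state clusters passed. TMM factors over the classes gave 0 classes and log2 ratios of 0.13 for NK-like and 0.0819 for macrophage-like cells. With an estimated correlation 0 gene lists passed, and 0 in CD8 T-like cells.

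With free RNA subtracted, Tnfrsf9 was at 0.0249 in CD8 T-like and −1.18 in macrophage-like cells, the MHC class II list in CD8 T-like cells had a median of −1.36, and the proliferation and melanoma lists in monocyte-like cells had −0.26 and −0.53. With monocyte and macrophage classes and the cluster led by Mmp12 and Adm pooled, Stmn1 was at −0.29, Birc5 at −0.19, Ccna2 at −0.36 and Gpnmb at −0.50. Without the cluster led by Lef1 and Satb1, 713 genes passed in CD8 T-like cells, the stem-like list had a median of 0.38, state cluster 2 a log2 ratio of −0.53, and the share of cells with a Tcf7 UMI differed by 1.25 percentage points.

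The labels do not say whether the replicate numbers pair libraries of different groups, so they were not used as pairs in the main tests. With the number as a block 550 genes passed in CD8 T-like, 145 in regulatory T-like and 10 in neutrophil-like cells. Deviations of libraries with the same number had a correlation of −0.145 in CD8 T-like cells, and with the crossed pairing 724 genes passed there, 340 in neutrophil-like cells and 8 of 12 classes.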

Other observations

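The test of NK-like cells at a minimum of 20 cells was chosen after the results were seen, as were the genes named from it. NK-like cells numbered 64, 55, 26 and 65 in isotype replicates 1 and 2 and triple replicates 1 and 2. Klrg1, a receptor of mature NK cells, rose from 63.3 and 77.5 CPM to 275 and 297 CPM (log2 fold change 2.05, SE 0.27, adjusted p = 0.00764). Several granzyme genes rose with it, Gzmc by 3.36 (adjusted p = 0.0319) and Gzmb by 1.63 (adjusted p = 0.0253), and Gzmd went from 10.5 and 4.3 CPM to 450 and 6096 CPM. The cytotoxic effector list as a whole did not pass (median 0.39, adjusted p = 0.168), with 6 of 16 members higher and 0 lower, 7 higher and 3 lower adjusted over the list alone, and Gzma at −0.39. Klf2 (−2.20), Cd27 (−2.11) and Bcl2 (−1.94), genes of resting or long-lived lymphocytes, fell, and Klrb1c, which encodes NK1.1, fell by 1.48 (adjusted p = 0.0319). In total 78 of 3432 genes passed with edgeR, 41 higher and 37 lower. The stem-like and memory list had 3 of 9 members lower, 7 adjusted over the list alone (median −1.30, adjusted p = 3.26e-07), and glycolysis 1 of 14 higher, 9 over the list alone (median 0.76, adjusted p = 2.51e-07), each with an adjusted p = 0.684 with an estimated correlation. The interferon gamma response did not pass in these cells (median −0.37, adjusted p = 0.225). Median UMIs per NK-like cell were 4386.5 and 3710 in the isotype and 8451.5 and 10700 in the triple libraries, and single libraries were not left out.

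The interferon gamma response was also followed within single clusters, where the make-up of a class varies less, a comparison chosen after the results were seen too. The clusters were built from the same counts without leaving these genes out, so the values within them are not independent of the response. In T cluster 2 all 15 measured members were positive, 10 of them called (median 1.18), and in T cluster 3, 11 of 12 were, 6 of them called (median 1.18). In monocyte-like cluster 2, 15 of 16 were positive with 11 called (median 1.06), in cluster 10 all 15 with 6 called (1.03), and in the unnamed cluster led by Mmp12 and Adm all 16 with 12 called (median 1.93). Of the macrophage-like clusters, cluster 6 had all 17 positive with 13 called (median 1.52), cluster 7 all 15 with 6 (1.24), cluster 5 all 16 with 3 (0.90) and cluster 17 14 of 15 with 7 (0.68), against 1.69 in the class. Cluster 0, the main monocyte-like cluster of the triple libraries, had 13 of 18 positive and 1 called (median 0.11). Gbp2 and Cxcl9, members of this list, were among its leading genes, so a small change within it was favoured beforehand. Macrophage-like cluster 8 and monocyte-like cluster 12 had 22 and 14 cells in isotype replicate 2, under the minimum of 30, and were not tested. CD4 conventional T cells chosen by a per-cell gate, with 30, 49, 79 and 31 cells, had 78 of 2887 genes past the edgeR threshold, 24 higher and 54 lower.

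Isotype replicate 2 held 138 B-like cells, against 35, 13 and 21 in isotype replicate 1 and triple replicates 1 and 2, and 321 CD8 T-like cells of the T cluster led by Lef1 and Satb1, against 118, 10 and 5. Whether lymph node tissue was part of this sample was not tested. With that cluster left out the stem-like and memory list of CD8 T-like cells had a median of 0.38 (adjusted p = 0.111), and without isotype replicate 2 the B-like share had a log2 ratio of −0.99 (adjusted p = 0.209).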
